A study of Mus musculus with 20 samples.

How the data were processed

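RNA-seq counts were analysed for 20 libraries of retrogradely labelled neurons from mouse ALM: 7 with the virus in the thalamus, 7 in the medulla (intermediate reticular nucleus), 3 in the superior colliculus and 3 in the pons. Per the labels, green fluorescent protein marked the thalamus, superior colliculus and pons cells and tdTomato the medulla cells, cells were sorted by hand, and cDNA was amplified before sequencing of single 100-base reads. The authors trimmed reads with Trimmomatic 0.36 and aligned them to GRCm38.p5 with STAR 2.5.3a. The deposited files hold read counts per gene from STAR, and the column that ignores strand was used, since 44.1% to 47.4% of reads fell on the first strand. Reads carry no molecular identifiers, so amplification copies are counted as reads. The series tables of all libraries were not used here.

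Gene reads ranged from 9.57 to 43.4 M reads per library, and 3 reads correspond to 0.0691 to 0.313 CPM, the floor used where a group has no read. Of all reads, 7.42% to 14.1% were unmapped, 4.35% to 5.61% mapped to several places, 12.2% to 26.0% fell in no gene and 1.63% to 2.82% in more than 1 gene; these were left out. Symbols, biotypes and coordinates came from GENCODE M21 on GRCm38, which named 48058 of 48526 identifiers. Runs were read from the library codes: replicates 1 to 3 of thalamus and medulla form the first, replicates 4 to 6 the second, superior colliculus and pons the third.

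The 18 standard libraries were fitted together in edgeR 4.0.16 with 1 mean per target (TMM, filterByExpr by group, robust dispersions, quasi-likelihood F test), and 6 pairs of targets were compared at a Benjamini-Hochberg adjusted p of 0.05; 14000 genes were tested. CPM values are means ± SD over libraries with TMM scaling. Summed levels of gene lists use TMM factors of all 20 libraries, so they are not on the same scale as CPM of single genes. Alternatives used DESeq2 1.42.0 and limma 3.58.1 (voom with quality weights). Software was R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

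Samples, comparisons, all but 5 of the alternatives and the rule for naming genes were set before the data were examined. Named between thalamus and medulla are the 12 called genes per direction with the largest changes, a mean log2 CPM of at least 3 and at least 5 of 6 libraries beyond the other group's median, up to 3 called members per list, and the 4 projection-type genes in both main comparisons. The other comparisons name 4 genes per direction, and where few genes were called, all of them and the 5 next in p. Left out of these choices by size or p were symbols starting with Gm and a digit or ending in Rik or -ps (with or without a digit). So were ribosomal protein and mitochondrially encoded genes, Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty. Genes outside these classes are called eligible for naming below. Some genes that these rules name are not reported here and were left out of the search for far libraries, while the counts of genes and the list tests still include them.

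Gene lists, 18 by symbol and 13 by name pattern, were corticofugal layer 5, projection-type, intratelencephalic, corticothalamic layer 6, layer 6b and near-projecting, inhibitory neuron, astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, vascular, fibroblast, blood, activity-induced, heat shock, interferon-response and neurofilament genes, deep-layer transcription factors, potassium, sodium and HCN, and calcium channels, glutamate, GABA, and monoamine and acetylcholine receptors, neuropeptides and their receptors, axon guidance genes, cadherins, synaptotagmins, and ribosomal, oxidative phosphorylation and mitochondrially encoded genes. The 25 lists with at least 3 tested members were tested by camera with a correlation of 0.01, then with an estimated correlation, and by fry. The list called neurofilament genes here also holds genes of large projection neurons. The score used log2 CPM with a prior count of 2 and an exact permutation test.

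The methods were tested on simulated data in which 200 genes changed. Between thalamus and medulla edgeR recovered 1%, 26.5% and 34% of 2-, 4- and 8-fold changes, and 73.1% of 8-fold changes among genes of at least 10 CPM. Between superior colliculus and pons it recovered 0%, 10% and 23.5%, and 51.7% of 8-fold changes among genes of at least 10 CPM. False calls were 0 to 5 with edgeR, 0 to 6 with limma-voom and 12 to 78 with DESeq2.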

Results

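Cortical neurons of the anterior lateral motor cortex (ALM), a frontal area of the mouse brain that takes part in planning movements, were labelled by a virus taken up through their axon terminals. The virus, rAAV2-retro, was injected into the thalamus, the medulla, the superior colliculus or the pons, so that the fluorescent cells later collected from ALM were those with axons at the injected site. Each RNA-seq library came from a pool of 50 to 120 hand-sorted cells from mice of about 56 days of age, and the replicates came from different mice. There were 6 standard libraries each for the thalamus and medulla targets and 3 each for the superior colliculus and pons targets. The submitters also named 1 thalamus and 1 medulla library as outliers, and these 2 were left out of the comparisons.

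Reads assigned to genes (M, mega) ranged from 9.57 to 43.4 M over the 18 standard libraries. The number of genes with at least 5 reads ranged from 8622 to 10531 in the first run (thalamus and medulla replicates 1 to 3). It ranged from 12339 to 14104 in the second run (replicates 4 to 6 of the same targets) and from 11434 to 13495 in the third run (superior colliculus and pons). Mitochondrial transcripts took 20.6% to 39.1% of gene reads. Xist, the transcript of the inactive X chromosome, was at 674 to 2892 CPM in every library while Ddx3y, Eif2s3y, Kdm5d and Uty of the Y chromosome did not exceed 0.211 CPM. All 36 pairs of replicates differed by far more than counting noise, with a chi-square per degree of freedom of 62.3 to 265; pairs across groups were not compared.

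Thalamus-projecting and medulla-projecting cells differed in Etv1, Npnt, Grin3a, Rorb and Rgs8, among other genes. Etv1 (ENSMUSG00000004151; chromosome 12, 38779380 to 38870484), an ETS-family transcription factor, was at 735 ± 289 CPM in thalamus-projecting cells and 84.0 ± 39.8 CPM in medulla-projecting cells (mean ± SD, n = 6 each), with a log2 fold change of 3.13 ± 0.31 (SE; adjusted p = 1.39e-07). Npnt (chromosome 3, 132881745 to 132950291), which encodes the matrix protein nephronectin, stood at 179 ± 48.1 against 2.51 ± 3.09 CPM, and Grin3a (chromosome 4, 49661611 to 49845744), an NMDA receptor subunit, at 80 ± 31.0 against 1.03 ± 1.55 CPM. In the other direction Rorb (chromosome 19, 18930605 to 19111196), an orphan nuclear receptor, was at 2.44 ± 2.09 CPM in thalamus-projecting and 62.9 ± 21.6 CPM in medulla-projecting cells (log2 fold change −4.66 ± 0.64, adjusted p = 3.52e-05). Rgs8 (chromosome 1, 153653025 to 153700323), a regulator of G protein signalling, was at 3.44 ± 1.82 against 103 ± 61.1 CPM.

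Of 14000 genes tested, 261 passed an adjusted p of 0.05 with edgeR, 137 higher in thalamus-projecting and 124 higher in medulla-projecting cells. The 6 thalamus and 6 medulla libraries did not overlap for 152 of the 261, and for 1.53% of all genes tested, where chance gives 0.217%. The 24 genes named next had to reach a mean log2 CPM of at least 3 over the 18 libraries. That leaves out genes with larger changes but few reads in 1 group. An example is Col8a1 (122 ± 55.0 against 0.162 ± 0.0790 CPM), with a log2 fold change of 9.56 in a fit of the 12 libraries alone. Under that rule the 12 thalamus-high genes with the largest changes had log2 fold changes from 2.81 (Auts2) to 6.20 (Grin3a). Besides those above they were the semaphorin Sema6a (179 ± 147 against 8.61 ± 6.06 CPM), the secreted glycoprotein gene Reln (161 ± 42.3 against 20.5 ± 14.8 CPM), the plasma membrane calcium pump Atp2b4 (421 ± 107 against 31.4 ± 34.2 CPM). The rest were the calcineurin regulator Rcan2, the glypican Gpc6, the ubiquitin ligase Pdzrn3, Sertm1, and AI504432, a long intergenic RNA. The 12 medulla-high genes under the same rule ran from −3.52 (Csdc2) to −6.79 (Wipf3). They included the bone morphogenetic protein Bmp3 (2.86 ± 3.68 against 83.0 ± 34.7 CPM), the calcium-binding protein gene Necab1 (4.03 ± 3.50 against 108 ± 48.2 CPM), Lypd1 (11.5 ± 7.48 against 170 ± 58.4 CPM). Others were the sialyltransferase St6galnac5 (12.3 ± 10.9 against 387 ± 293 CPM), the transcription factor Neurod6, Astn2, the activin receptor Acvr1c and the glycolytic enzyme Aldoc. The call of Gpc6 was lost in 14 of 27 alternative settings and that of Acvr1c in 6. All 6 libraries of the higher group lay above the other group's median for each of these 24 genes.

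The difference appeared in both runs of these targets. All 210 called genes that were tested in both runs had the same sign in each, and 162 of them had an unadjusted p under 0.05 in both. They were called with the libraries of both runs, so that agreement is partly fixed in advance. Of genes tested in both runs, the 24 called in the first run alone all had the same sign in the second. Of 275 called in the second run alone, 266 had the same sign in the first. Fitted alone, the first run called 24 genes and the second 308, with 18 of the 9245 genes tested in both runs called in each. No gene passed a test of run by target in edgeR (0 of 10757, 780 at an unadjusted p under 0.05, smallest adjusted p = 0.399; this test was run in edgeR alone). A split of the 12 libraries by run instead of target called 473 genes, so the run is a large source of difference; it is balanced over the targets. A fit of these 12 libraries alone called 122 genes, and 160 with run as a covariate. Without medulla replicates 2, 3 and 6, which held the most oligodendrocyte transcripts of that group, 142 genes were called, while the median absolute log2 fold change of the called genes went from 3.28 to 3.11.

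Genes that earlier single-cell work on this area linked to projection type followed their targets for 3 of the 4 tested. Npnt and Npsr1, the receptor of neuropeptide S, were higher in thalamus-projecting cells, Npsr1 at 75.4 ± 95.3 against 1.34 ± 3.11 CPM (n = 6 each, adjusted p = 0.0367). The Npsr1 call was lost in 9 of 27 settings, 7 of them fits without 1 library. Replicate 2, at 268.1 CPM, raised the thalamus mean of Npsr1, but the call was kept without that library. The other thalamus libraries were at 19.03 to 57.85 CPM, above every medulla library. Slco2a1, a prostaglandin transporter, was higher in medulla-projecting cells at 41.3 ± 20.95 against 0.817 ± 1.93 CPM (log2 fold change −5.56 ± 1.09, adjusted p = 0.00357). Hpgd, a prostaglandin dehydrogenase, was at 1.80 ± 2.98 CPM in thalamus and 0.183 ± 0.449 CPM in medulla libraries and was not called (adjusted p = 0.497). Adjusted over the list alone the calls were the same in number, 2 higher and 1 lower. The camera test put the list higher in thalamus-projecting cells (adjusted p = 0.0217; 0.114 as adjusted p with an estimated correlation).

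Markers of corticofugal layer 5 neurons were present in all groups. Bcl11b and Fezf2, transcription factors of neurons projecting out of the cortex and named here after their values were seen, were at 152 ± 40.3 and 364 ± 205 CPM in thalamus-projecting and at 198 ± 76.3 and 236 ± 90.6 CPM in medulla-projecting cells. Neither was called. Of 13 corticofugal genes tested, 2 were higher in thalamus-projecting cells, the transcriptional repressor Bcl6 (205 ± 49.6 against 70.8 ± 22.5 CPM) and the calmodulin-binding Pcp4 (100.5 ± 35.2 against 36.2 ± 16.2 CPM). The Pcp4 call was lost in 9 of 27 settings. The other 11 were not called by edgeR, while DESeq2 and limma-voom called 3 of the 13 each. Adjusted over the list alone in edgeR, 4 were higher. The list as a whole was higher in thalamus-projecting cells (camera adjusted p = 0.0315; adjusted p = 0.0841 with an estimated correlation), and it passed in 9 of 17 alternative settings. Intratelencephalic genes, which mark neurons projecting within the cortex, split: of 9 tested, 3 were higher in thalamus-projecting cells, among them Etv1 and the semaphorin receptor Plxnd1. Lower were 3, Rorb, Deptor and Rspo1, with 4 and 3 adjusted over the list alone (camera adjusted p = 0.284). Deep-layer transcription factors also split, with 2 of 27 higher and 4 lower (8 and 5 adjusted over the list alone, camera adjusted p = 0.284).

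Of 8 genes of corticothalamic layer 6 neurons tested, 2 were called lower in thalamus-projecting cells, and 6 of the 8 had a lower estimate (camera adjusted p = 0.00886; adjusted p = 0.0514 with an estimated correlation). Syt6, a synaptotagmin, was at 0.0989 ± 0.242 CPM with no read in 5 of 6 thalamus libraries, against 37.1 ± 14.5 CPM in medulla-projecting cells (log2 fold change −8.29 ± 1.04, adjusted p = 1.12e-05). Hs3st4, a heparan sulfate sulfotransferase, was at 4.43 ± 4.07 against 32.4 ± 17.4 CPM, a call lost in 17 of 27 settings. Adjusted over the list alone 1 was higher and 3 lower. Among 4 layer 6b and near-projecting genes tested, Nr4a2, a nuclear receptor (0.167 ± 0.198 against 10.1 ± 6.82 CPM), and Ccn2, a secreted matricellular protein (0.00761 ± 0.0186 against 2.88 ± 3.22 CPM), were lower, the Ccn2 call being lost in 14 of 23 settings. The same number were lower adjusted over the list alone (camera adjusted p = 0.0593, fry adjusted p = 0.0129).

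The neurofilament genes Nefm and Nefl were lower in thalamus-projecting cells. Nefm was at 627 ± 119 against 1288 ± 171 CPM (log2 fold change −1.04 ± 0.17, adjusted p = 2.32e-04) and Nefl at 717 ± 55.6 against 1129 ± 111 CPM (−0.65 ± 0.15, adjusted p = 0.0165), both subunits of the axonal intermediate filament. The Nefl call was lost in 5 of 27 settings. Of 7 genes tested on the list of neurofilament and large projection neuron genes, 2 were called, and 4 adjusted over the list alone, all lower in thalamus-projecting cells. It was the list that held with an estimated correlation (camera adjusted p = 1.16e-04; adjusted p = 0.0143 with an estimated correlation). The exons of Nefm and Nefl overlap on opposite strands over 1108 bases of chromosome 14. Reads there fall in more than 1 gene in these unstranded counts and were left out of both.

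**Figure D1:**
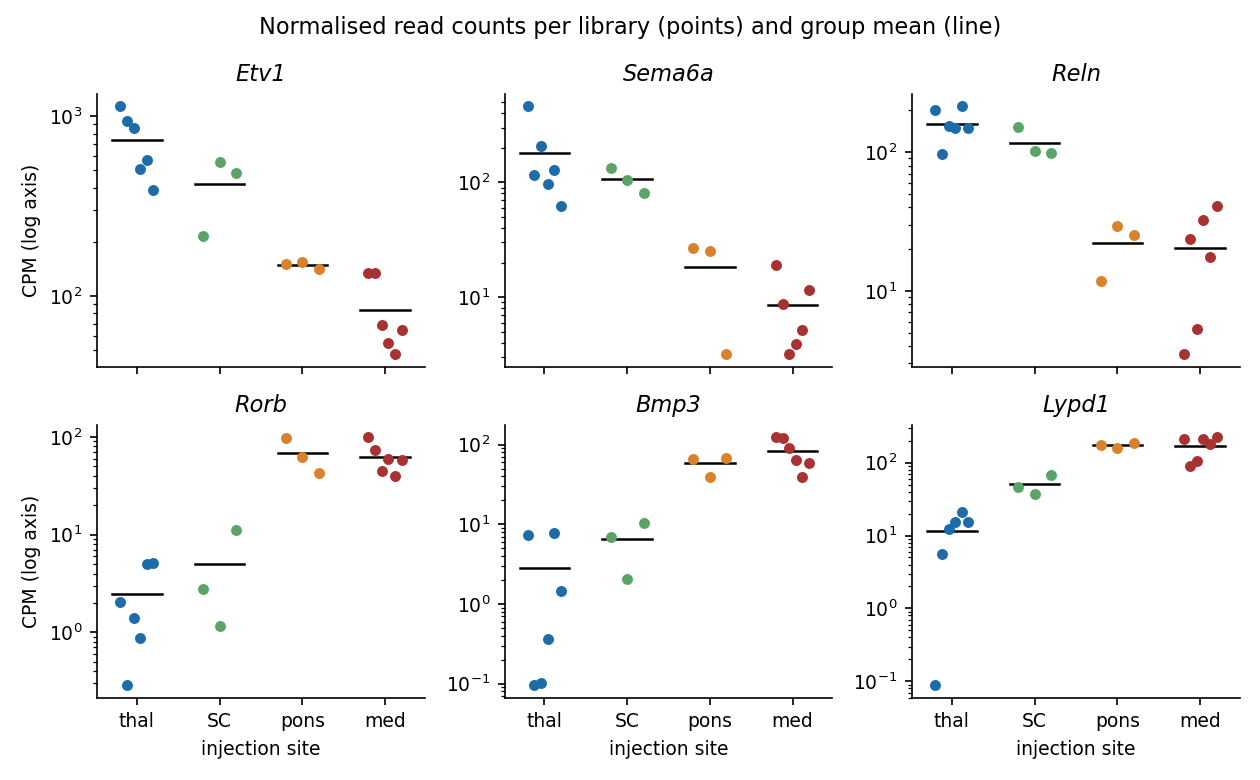
CPM of 6 genes in each of the 18 standard libraries, on log axes, grouped by injection site (thal, thalamus; SC, superior colliculus; med, medulla); points are libraries and lines group means. Etv1, Sema6a and Reln had their highest means in thalamus libraries, and Rorb, Bmp3 and Lypd1 had higher means in pons and medulla than in thalamus and superior colliculus libraries.

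Among ion channel and receptor genes, single members were called in both directions, and no such list passed the camera test, which looks for a shift in 1 direction. Of 63 potassium channel genes, Kcng3 (48.4 ± 47.9 against 0.510 ± 0.983 CPM) and Kcnc2 (21.2 ± 19.8 against 0.211 ± 0.424 CPM) were higher in thalamus-projecting cells. Kcnab1 (0.931 ± 0.642 against 18.2 ± 7.89 CPM) and Kcnip1 were lower, with 8 and 3 adjusted over the list alone (camera adjusted p = 0.847). The median and the mean change differ in sign for the potassium channels (−0.01 and 0.22) and for the glutamate receptors (−0.05 and 0.02). Of 22 genes on the voltage-gated calcium channel list, Cacna1e, the R-type channel subunit, was lower (452 ± 86.2 against 1071 ± 209 CPM), as was Cacnb4 (389 ± 134 against 716 ± 270 CPM). Cacng3, a list member that need not serve a calcium channel, was higher (113 ± 61.1 against 36.0 ± 24.1 CPM; camera adjusted p = 0.108, with 1 higher and 3 lower adjusted over the list alone). Scn4b, an auxiliary sodium channel subunit, was the 1 call of 14 sodium and HCN channel genes (37.9 ± 18.6 against 113 ± 36.8 CPM), with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.487). Among 22 glutamate receptor genes, 2 were higher, among them Grin3a, and Grm3 (30.9 ± 20.4 against 126 ± 98.1 CPM) and Grik3 (42.1 ± 22.3 against 124 ± 38.3 CPM) were lower, as many as adjusted over the list alone (camera adjusted p = 0.875). Of 28 monoamine and acetylcholine receptor genes, the nicotinic subunit Chrnb3 (12.6 ± 12.8 against 0.0407 ± 0.0717 CPM) and the adrenergic receptor Adra1a (259 ± 96.8 against 123 ± 16.1 CPM) were higher. There were 5 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.386). Of 23 neuropeptide and receptor genes, Npsr1 and the relaxin receptor Rxfp1 were higher, with 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.823). The Rxfp1 call was lost in 16 of 23 settings and the Npsr1 call in 9 of 27. Among the channels and receptors above, the calls of Cacnb4, Cacng3 and Adra1a were lost in 11, 8 and 7 of 27. Rxfp1 had no read in any medulla library and 1.34 ± 1.02 CPM in thalamus libraries, at least 6.28-fold higher than a floor of 3 reads per library. GABA receptors had 0 of 15 called by edgeR (2 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom; camera adjusted p = 0.358, 0 adjusted over the list alone).

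Genes that guide axons and join cells went both ways as well. Of 58 axon guidance genes, 4 were higher in thalamus-projecting cells and 2 lower, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.106). Sema6a and Sema3c, a secreted semaphorin (139 ± 65.7 against 24.4 ± 12.4 CPM), were higher, and the semaphorin receptor Plxna4 was lower (125 ± 36.5 against 300 ± 64.0 CPM). Of 27 cadherins and protocadherins, Cdh7 (215 ± 143 against 55.3 ± 35.4 CPM) was higher and Cdh13 (55.8 ± 17.9 against 166 ± 37.6 CPM) lower, with 2 and 1 adjusted over the list alone (camera adjusted p = 0.487). Syt6 was the 1 call of 15 synaptotagmins (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.386, fry adjusted p = 0.0438).

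Housekeeping and stress lists did not pass the camera test between thalamus-projecting and medulla-projecting cells with the 18 libraries. Mitochondrially encoded genes passed with a replicate block, and oxidative phosphorylation genes passed without medulla replicate 3 or thalamus replicate 4. Of 15 activity-induced genes, Nr4a3 was lower in thalamus-projecting cells (7.44 ± 6.09 against 52.3 ± 24.0 CPM), 2 were lower adjusted over the list alone, and the camera adjusted p was 0.601, with a median change of 0.20 but a mean of −0.04. Of 75 ribosomal protein genes, Rps15a was lower (41.8 ± 11.7 against 106 ± 38.6 CPM; 1 adjusted over the list alone, camera adjusted p = 0.618), a gene with processed copies elsewhere in the genome, so that its count is uncertain, and its call was lost in 11 of 27 settings. By edgeR 0 of 9 heat shock genes (0 at an unadjusted p under 0.05; camera adjusted p = 0.739), 0 of 87 nuclear oxidative phosphorylation genes (6; 0.143) and 0 of 7 mitochondrially encoded genes (0; 0.487) were called, and as few adjusted over the list alone. DESeq2 called 2 of the 87 and limma-voom 0, and both called 0 of the other 2 lists.

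Superior colliculus-projecting and pons-projecting cells, compared within 1 run, differed in Col8a1, the gene with the smallest p. This gene (ENSMUSG00000068196; chromosome 16, 57624258 to 57754737) encodes a short-chain collagen and was at 80.9 ± 10.7 CPM in superior colliculus-projecting and 1.498 ± 1.92 CPM in pons-projecting cells (n = 3 each; log2 fold change 5.75 ± 0.76, adjusted p = 2.78e-04). Its levels were 122 ± 55.0 CPM in thalamus-projecting and 0.162 ± 0.0790 CPM in medulla-projecting cells (n = 6 each). It was the 1 call of edgeR among 14000 genes, with 669 genes at an unadjusted p under 0.05, and 13.2% of genes without overlap between the groups, where chance gives 10%. DESeq2 called 68 genes and limma-voom 61; with simulated data of this size edgeR recovered 23.5% of 8-fold changes and 10% of 4-fold changes. The gene 2510009E07Rik, not eligible for naming by its symbol, had an unadjusted p of 5.73e-05 in edgeR, under that of Rorb, and was not called. Among eligible genes, the 5 with the next smallest p were not called by edgeR in the main fit: Rorb at 5.01 ± 5.34 against 67.9 ± 27.9 CPM, Grin3a at 102 ± 70.7 against 3.89 ± 3.75 CPM, and 3 more. These were Cntnap2, a neurexin-family adhesion protein, at 688 ± 169 against 250 ± 37.5 CPM, Sema3c at 144 ± 39.2 against 35.4 ± 7.44 CPM and Pdzrn3 at 126 ± 102 against 12.3 ± 1.40 CPM (adjusted p of 0.655 to 0.724). In alternative settings Grin3a and Pdzrn3 were called in 6 of 17 each and Cntnap2 in 4 of 16. Npnt (103 ± 27.4 against 10.2 ± 7.24 CPM), Npsr1 (29.4 ± 9.37 against 2.42 ± 3.41 CPM), Slco2a1 (10.6 ± 2.34 against 41.4 ± 20.8 CPM) and Hpgd (0.00954 ± 0.0165 against 0.578 ± 0.878 CPM) were not called by edgeR in that fit either, each with an adjusted p of 1. Npnt was called in 5 of 17 alternative settings and Npsr1 in 1 of 17.

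The genes that separated thalamus-projecting from medulla-projecting cells moved together in this comparison. A fit of the 12 thalamus and medulla libraries alone called 122 genes, 63 higher in thalamus-projecting and 59 higher in medulla-projecting cells, and none of the 6 superior colliculus and pons libraries took part in that choice. Of these, 118 had the same sign between superior colliculus-projecting and pons-projecting cells (96.7%), where 54.7% of the genes not called did. Tested in edgeR and adjusted over these 122 genes alone, a choice made after seeing the data, 33 were higher in superior colliculus-projecting and 13 higher in pons-projecting cells, all 46 with the same sign as between thalamus and medulla. Across the 122 genes, which are not independent replicates, the differences of mean log2 CPM had a correlation of 0.887 and a slope through 0 of 0.499. No gene passed a test of whether the thalamus to medulla difference exceeded the superior colliculus to pons difference in edgeR, the 1 tool used for it (0 of 14000, 709 at an unadjusted p under 0.05, smallest adjusted p = 0.116 for Stk17b).

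A score was made for each library as the mean log2 CPM of the 63 thalamus-high genes minus that of the 59 medulla-high genes. It was 1.26 ± 0.41 in superior colliculus-projecting and −2.60 ± 0.57 in pons-projecting cells (n = 3 each), a difference of 3.87 with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give. Thalamus-projecting cells scored 3.45 ± 0.74 and medulla-projecting cells −4.25 ± 0.44 (n = 6 each), values that are inflated because the genes were chosen on those libraries. Scored with genes chosen in the other run, they were at 3.27 ± 1.05 and −3.59 ± 1.39. These values pool 2 gene sets, from the 24 calls of the first run and the 308 of the second. Thalamus libraries of the first run were at 2.21 to 2.55 and those of the second at 3.53 to 4.605. The SD therefore includes the change of genes, and the means are not on the scale of the first values. On the first scale superior colliculus-projecting cells lay 71.6% and pons-projecting cells 21.4% of the way from the medulla to the thalamus mean, with the run of these 2 groups not separable from their targets.

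**Figure D2:**
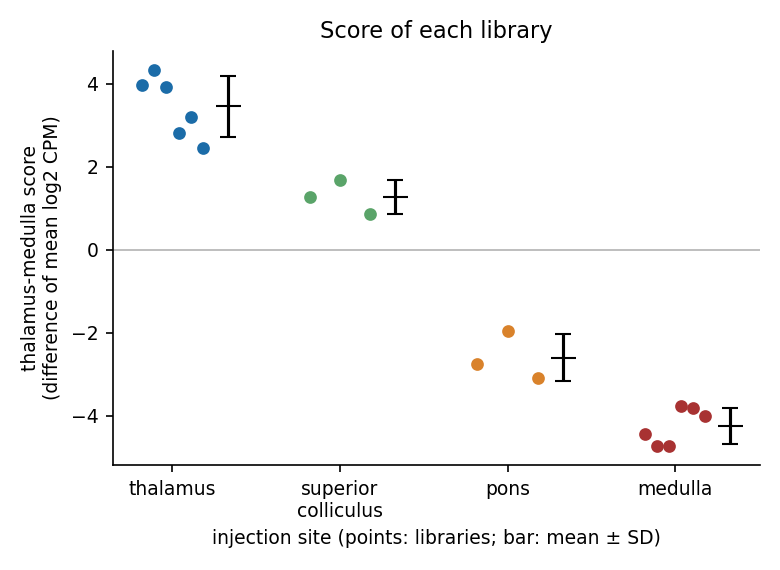
Thalamus-medulla score of each of the 18 standard libraries (difference of mean log2 CPM between 63 thalamus-high and 59 medulla-high genes), by injection site; points are libraries and bars the mean ± SD. The superior colliculus libraries lie between 0.85 and 1.67 and the pons libraries between −3.08 and −1.97.

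**Figure D3:**
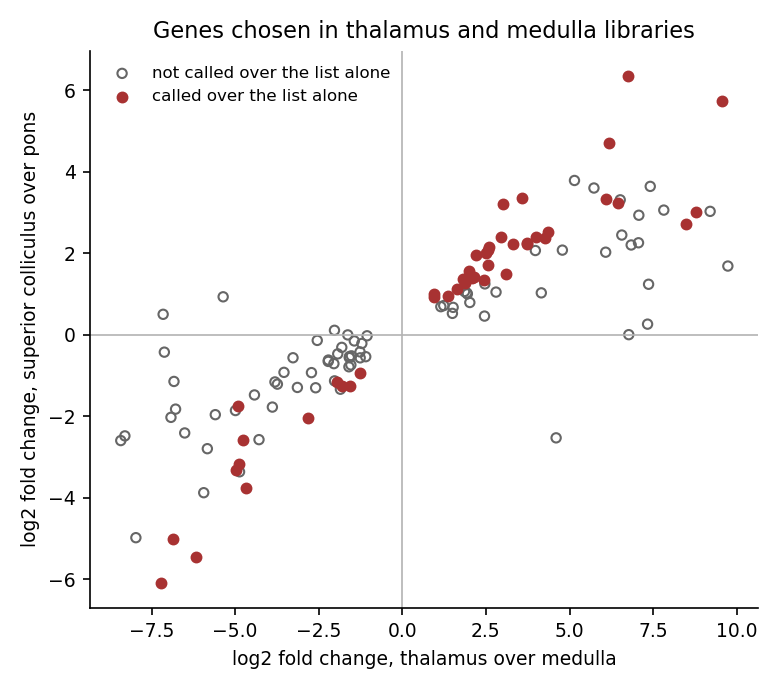
Log2 fold change between superior colliculus-projecting and pons-projecting cells (vertical axis) against that between thalamus-projecting and medulla-projecting cells (horizontal axis) for the 122 genes chosen in the 12 thalamus and medulla libraries; filled points are the 46 genes called when adjusted over these genes alone. Of the 122 points 118 have the same sign on both axes.

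Activity-induced genes were lower in superior colliculus-projecting than in pons-projecting cells as a group. Of 15 tested 13 were lower, and the summed level was 287 ± 57.9 CPM against 633 ± 104 CPM (n = 3 each; camera adjusted p = 6.65e-07, and adjusted p = 8.99e-04 with an estimated correlation). Members of the list, chosen after their values were seen, were the transcription factor Egr1 at 196 ± 50.2 against 339 ± 65.8 CPM, the phosphatase Dusp1 at 27.0 ± 5.03 against 102 ± 21.1 CPM and Nr4a3 at 15.2 ± 10.2 against 63.0 ± 13.8 CPM. None of the 15 was called by edgeR (3 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom) or adjusted over the list alone. The summed level of these genes was 359 ± 115 CPM in thalamus-projecting and 419 ± 179 CPM in medulla-projecting cells (n = 6 each).

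GABA receptor genes were higher as a group in superior colliculus-projecting than in pons-projecting cells, by a median of 0.29 on the log2 scale with 14 of 15 above 0 (camera adjusted p = 0.00164; adjusted p = 0.181 with an estimated correlation, fry adjusted p = 0.267). By edgeR 0 of the 15 were called, 0 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Corticothalamic layer 6 genes were lower as a group, by a median of −1.15 (camera adjusted p = 0.0424; adjusted p = 0.146 with an estimated correlation). Syt6 was at 5.21 ± 3.82 against 29.1 ± 2.37 CPM, and 0 of 8 called by edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom). The other 22 lists did not pass the camera test in this comparison. Adjusted over the list alone, members passed on the intratelencephalic list (3 higher, 1 lower), among deep-layer transcription factors (3 higher, 1 lower), axon guidance genes (2 higher), glutamate receptors (1 higher) and projection-type genes (1 higher). The median, the mean and the test differ in sign for the projection-type, oligodendrocyte, neurofilament, calcium channel, neuropeptide and ribosomal lists, none of which passed.

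The other 4 comparisons set the third run against the first 2 and cannot separate target from run. Superior colliculus-projecting cells had more of the adhesion protein gene Alcam (180 ± 20.3 CPM, n = 3) than thalamus-projecting cells (48.0 ± 13.7 CPM, n = 6; log2 fold change 1.91 ± 0.34, adjusted p = 0.0246). They had more Wipf3, which binds actin regulators (42.1 ± 11.5 against 0.747 ± 1.24 CPM) and more Syt6 (5.21 ± 3.82 against 0.0989 ± 0.242 CPM). These 3 were the calls of edgeR for that pair among 14000 genes, with 916 at an unadjusted p under 0.05 and 2.32% of genes without overlap, where chance gives 2.38%. DESeq2 called 45 genes higher in superior colliculus-projecting cells and 96 lower. None of the 3 was called by edgeR without thalamus replicate 1, thalamus replicate 3 or superior colliculus replicate 1. Not called by edgeR in the main fit, with the next smallest p among eligible genes, were Rgs5, Rgs8, Plod2, Astn2 and Mal, a myelin protein gene at 0.0528, 46.8 and 4.18 CPM in the superior colliculus libraries and 0 reads in all thalamus libraries (adjusted p = 0.135). In alternative settings Plod2 and Astn2 were called in 2 of 18 each and Mal in 2 of 16. Against medulla-projecting cells, superior colliculus-projecting cells had 51 genes higher and 5 lower with edgeR, but 128 higher and 199 lower with DESeq2. A replicate block fitted to 3 libraries per group gave 29 and 15. Grin3a (102 ± 70.7 against 1.03 ± 1.55 CPM), Pdzrn3, Sema6a (106 ± 25.7 against 8.61 ± 6.06 CPM) and Npnt (103 ± 27.4 against 2.51 ± 3.09 CPM) led the higher genes. Rorb, the cation exchanger Slc24a2 (498 ± 128 against 1666 ± 503 CPM), Agap1 and the protein kinase Prkca (140 ± 5.66 against 334 ± 64.0 CPM) led the lower ones. Of 18 settings each, the calls of Prkca were lost in 11, of Agap1 in 10 and of Rorb in 6, and in the thalamus pair those of Syt6 in 10 and of Alcam and Wipf3 in 8. All 56 called genes separated the groups without overlap, as did 3.96% of genes tested, where chance gives 2.38%; 27 were called without superior colliculus replicate 2.

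Pons-projecting cells had 43 genes higher and 11 lower than thalamus-projecting cells with edgeR, but 129 and 119 with DESeq2 and 31 and 26 with the 2 groups alone. A replicate block fitted to 3 libraries per group gave 43 and 61. Rorb (67.9 ± 27.9 CPM, n = 3, against 2.44 ± 2.09 CPM, n = 6; log2 fold change 4.78 ± 0.68, adjusted p = 3.00e-04), Wipf3 (93.1 ± 25.4 against 0.747 ± 1.24 CPM), Necab1 (99.9 ± 29.8 against 4.03 ± 3.50 CPM) and St6galnac5 were higher. Rcan2 (8.65 ± 2.62 against 130 ± 50.9 CPM), Reln (22.1 ± 9.18 against 161 ± 42.3 CPM), Sema6a and AI504432 were lower. Of 18 settings each, the calls of AI504432, Sema6a, Rcan2 and Reln were lost in 6, 5, 4 and 3. All 54 separated the groups without overlap, and 4.57% of genes tested did, where chance gives 2.38%; 25 were called without pons replicate 1 and 26 without pons replicate 3. Between pons-projecting and medulla-projecting cells DESeq2 called 23 genes higher in pons-projecting cells and 33 lower, and a replicate block gave 0 and 1. The main fit in edgeR called 5 genes, all higher in pons-projecting cells at low levels. They were the kinase Stk17b (6.04 ± 2.26 against 0.141 ± 0.194 CPM, adjusted p = 0.00123), the adhesion protein Mdga1 (5.50 ± 6.52 against 0.0226 ± 0.0553 CPM), the sorting receptor Sorcs3 (3.57 ± 5.98 against 0.0114 ± 0.0280 CPM), Col8a1 (1.498 ± 1.92 against 0.162 ± 0.0790 CPM) and the immunoglobulin-family Igsf3 (2.28 ± 2.47 against 0.0497 ± 0.106 CPM). Thalamus-projecting cells held far more of each, from 20.4 ± 4.88 CPM of Sorcs3 to 122 ± 55.0 CPM of Col8a1 (n = 6). The groups did not overlap for 2.14% of genes tested, where chance gives 2.38%. Sorcs3 rests on pons replicate 1 at 10.47 CPM, the others being at 0.1657 and 0.07658 CPM, and the calls of Sorcs3, Mdga1 and Igsf3 were lost without that library. The Igsf3 call was lost in 11 of 18 settings and the Stk17b call in 2, and those of Col8a1, Sorcs3 and Mdga1 in 9, 7 and 5 of 16. Without medulla replicate 2, 3 or 6 the count of this pair was 1. Gpc5, Tbx22, Ptgfrn, Kcng3 and Acer2 had the next smallest p among eligible genes without being called by edgeR in the main fit (adjusted p of 0.138 to 0.285). In alternative settings Kcng3 and Acer2 were called in 3 of 18 each, Ptgfrn in 3 of 17 and Gpc5 in 2 of 16.

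Gene lists in these 4 comparisons carry the same mixture of run and target. Activity-induced genes were higher in pons-projecting than in thalamus-projecting cells (camera adjusted p = 0.00457; adjusted p = 0.0332 with an estimated correlation) and than in medulla-projecting cells (0.00390; adjusted p = 0.0309 with an estimated correlation). Neurofilament and large projection neuron genes were lower in pons-projecting than in medulla-projecting cells (0.00352; adjusted p = 0.0309 with an estimated correlation), and corticothalamic layer 6 genes higher in pons-projecting than in thalamus-projecting cells (0.00481; adjusted p = 0.0391 with an estimated correlation). The other 13 list calls of these comparisons did not hold with an estimated correlation (adjusted p = 0.0653 with an estimated correlation for vascular genes between pons-projecting and thalamus-projecting cells, the smallest).

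Transcripts of other brain cell types were measured as a check of the sort. Oligodendrocyte genes summed to 157 ± 171 CPM in medulla libraries, with a range of 13.9 to 467 CPM, against 53.6 ± 8.29 CPM in thalamus libraries (n = 6 each). They summed to 145 ± 92.3 CPM in superior colliculus and 170 ± 137 CPM in pons libraries (n = 3 each). Ermn (0.0147 ± 0.0359 against 12.4 ± 19.7 CPM, adjusted p = 0.0108) and Cldn11 (0.0147 ± 0.0359 against 4.30 ± 4.73 CPM), which encode myelin proteins, were lower in thalamus than in medulla libraries among 10 tested, 7 adjusted over the list alone. The list's camera adjusted p was 0.00886, with an adjusted p of 0.417 with an estimated correlation, 0.0861 without medulla replicate 2 and a fry adjusted p of 0.260. The Cldn11 call was lost in 13 of 22 settings and the Ermn call in 4 of 21. Vascular genes summed to 13.9 ± 15.4 CPM in thalamus, 54.9 ± 33.1 in medulla, 16.2 ± 11.1 in superior colliculus and 59.7 ± 11.8 in pons libraries (camera adjusted p = 0.103 for the last pair). Of 3 vascular genes tested Rgs5, a pericyte gene, was lower in thalamus-projecting cells (0.345 ± 0.707 against 40.8 ± 22.5 CPM; 1 adjusted over the list alone, camera adjusted p = 0.0133, adjusted p = 0.0841 with an estimated correlation). Rgs5, at 46.5 ± 18.1 CPM in pons libraries, made up most of the differences in the vascular sums. The 3 genes had a mean correlation of 0.0629 around group means, against 0.504 for oligodendrocyte genes. The sums therefore do not show that vascular cells were carried along. Of 5 astrocyte genes tested Aldoc was lower (2.62 ± 1.59 against 36.6 ± 17.9 CPM; 2 adjusted over the list alone, camera adjusted p = 0.0534, fry adjusted p = 0.0129).

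Other lists had under 3 genes tested, and only their summed levels are given. Inhibitory neuron genes were at 0.741 ± 1.25 CPM in thalamus, 5.47 ± 10.3 in medulla, 0.822 ± 1.35 in superior colliculus and 1.56 ± 1.48 in pons libraries. Of these Erbb4, a neuregulin receptor, was lower in thalamus than in medulla libraries (0.00559 ± 0.0137 against 5.39 ± 10.3 CPM, adjusted p = 0.0445) on the strength of medulla replicate 2 at 25.9 CPM. Microglia genes were at 2.77 ± 2.83, 2.90 ± 1.61, 2.59 ± 0.921 and 2.13 ± 0.378 CPM in the same order. Oligodendrocyte precursor genes were at 0, 1.13 ± 1.98, 0.0197 ± 0.0172 and 1.47 ± 2.54 CPM, and blood genes at 0.298 ± 0.4664, 0.3302 ± 0.396, 0.0360 ± 0.0425 and 0.0371 ± 0.0643 CPM. Fibroblast genes were at 4.78 ± 9.66, 0.379 ± 0.481, 0 and 0.0107 ± 0.0186 CPM, and interferon-response genes at 9.92 ± 6.35, 9.38 ± 10.6, 13.3 ± 9.21 and 4.57 ± 3.02 CPM. For comparison, astrocyte genes summed to 602 ± 90.7 to 798 ± 167 CPM across the groups.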

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

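The tests in this part, of splits of the samples, of the reporter and of oligodendrocyte RNA, were written down after the results were seen.

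The 261 genes between thalamus-projecting and medulla-projecting cells were weighed against 3 explanations. A chance division of the libraries is unlikely, since 1 of 100 splits drawn from 462, the real one, reached 261 and the highest other drawn called 36. Chance is not excluded, as most splits were not drawn and the libraries differ by run. The split by run, not among those drawn, called 473; within runs 24 and 308 genes were called, and the 12 libraries alone gave 122, or 160 with run as a covariate. The targets also differ in fluorescent protein, but 96.72% of genes chosen in these libraries kept their sign between superior colliculus and pons libraries, all green, against 54.72% of other genes; an effect of the reporter on genes not shared in that way could remain. Without medulla replicates 2, 3 and 6, 99.61% of the 258 called genes tested kept their sign and the median absolute log2 fold change went from 3.28 to 3.11, but the genes were called with the libraries that remain, so how many calls owe to oligodendrocyte RNA is left open.

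Oligodendrocyte genes had a mean correlation of 0.5038 across libraries around the group means. That is consistent with RNA of oligodendrocytes carried along in some libraries, so their difference may not belong to the neurons.

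Single libraries stood far from the rest of their group in 25 of 119 groups of values tested, where chance gives about 6. That excess is partly fixed in advance, since Ermn, Cldn11, Ccn2 and Erbb4 had 1 read among all thalamus libraries, under the floor of 3 reads. The chance figure also assumes a normal spread, which CPM on a linear scale need not follow, so the excess is not read as aberrant libraries. High values among thalamus libraries, in CPM, were Syt6 at 0.5933, Rgs5 at 1.78 and Ccn2 at 0.04564 in replicate 4, Sema6a at 463.5, Ermn at 0.08792 and Cldn11 at 0.08792 in replicate 1, Kcng3 at 143.4 in replicate 3, Cacng3 at 235.6 and Npsr1 at 268.1 in replicate 2, Slco2a1 at 4.758 and Erbb4 at 0.03351 in replicate 6, and Hpgd at 7.554 in replicate 5. Cdh13 was low at 20.85 in replicate 2. High values among medulla libraries were St6galnac5 at 975.5, Atp2b4 at 97.28, Grm3 at 325.6 and Cacnb4 at 1251 in replicate 1, Erbb4 at 25.92 in replicate 2, Rgs8 at 218.9 and Kcnc2 at 1.059 in replicate 3, Rcan2 at 29.19 in replicate 4, Grin3a at 4.00, Kcng3 at 2.506 and Hpgd at 1.099 in replicate 5, and Npsr1 at 7.687 in replicate 6. The thalamus library named an outlier by the submitters had 1797 genes above every standard library, where standard libraries had 260 to 1704 above all others. Its reads fell on fewer genes, 6400 with at least 5 reads against 8622 or more in standard libraries. The count of 1797 therefore need not mean higher expression.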

How the results depend on the processing

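All alternatives were planned except 5, each said to be chosen after seeing the data. Between thalamus-projecting and medulla-projecting cells, 261 genes became 581 without a filter, 705 with DESeq2, 426 with limma-voom, 122 with the 2 groups alone, 160 with the 2 groups alone and run as a covariate, and 24 in the first run alone; chosen after seeing the data, 142 without medulla replicates 2, 3 and 6, 164 with oligodendrocyte genes as a covariate and 210 for the second run fitted with the third. Leaving out 1 library gave 187 to 264. Between superior colliculus-projecting and pons-projecting cells, 1 became 21 without a filter, 68 with DESeq2, 61 with limma-voom, 17 with the 2 groups alone, 17 with a replicate block, and, chosen after seeing the data, 46 among the thalamus-medulla genes and 1 with oligodendrocyte genes as a covariate. Against thalamus-projecting cells, the 3 of superior colliculus became 0 by library size, 65 without a filter, 141 with DESeq2, 55 with limma-voom, 0 with the 2 groups alone, 6 with a block and 0 to 5 leaving out 1 library. The 54 of pons became 152, 34 with the outlier libraries, 248 with DESeq2, 433 with limma-voom, 104 with a block and 25 to 57. Against medulla-projecting cells, the 56 of superior colliculus became 165 without a filter, 36 with the outlier libraries, 327 with DESeq2, 287 with limma-voom, 27 with the 2 groups alone and 27 to 75. The 5 of pons became 42, 3 at CPM over 1 in 6 libraries, 56 with DESeq2, 10 with limma-voom, 0 with the 2 groups alone, 1 with a block and 1 to 6. The score difference was 2.98 with genes of both runs. Gene list calls with an estimated correlation were 1 of 6 between thalamus and medulla (4 to 9 leaving out 1 library) and 1 of 3 between superior colliculus and pons. Erbb4 turned to 1.28 without medulla replicates 2, 3 and 6. Of planned repeats of named genes and lists, 1873 were the same, 287 weaker and 55 stronger.

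Replicate numbers were not taken to pair libraries. Same-numbered thalamus and medulla libraries correlated at 0.0441 to 0.138 around group means, with 4 of 6 pairs over 0.1 and 4 of 6 best with their own number (median 0.124, other pairs of the same run 0.0893), and 0 of 6 over 0.1 around group and run means. The 12 libraries gave 204 genes with the block and 122 without.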

Other observations

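The splits of the samples were written down as tests after the results were seen, and the comparison of single genes with a mixture of cells before its values were seen.

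Superior colliculus-projecting cells resemble thalamus-projecting cells and pons-projecting cells resemble medulla-projecting cells in the genes that part the latter pair, with 96.72% of them of the same sign. Etv1, Npnt, Sema6a, Reln and Col8a1 lie at the thalamus end and Rorb, Bmp3 and Lypd1 at the medulla end. A hypothesis is that pools labelled from the superior colliculus and pons may hold both kinds of cell, since single neurons can reach several targets.

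The prediction was that 1 share of each kind for all genes leaves no shared order of genes in superior colliculus to pons ratios. A correlation of the 3 ratios, each of separate libraries, above that of shuffled genes was to speak against it. This prediction holds only for genes absent from the other kind of cell. For 21 genes nearly restricted to medulla-projecting cells the mean correlation was 0.08767, under the 95th percentile of shuffled genes of 0.2155 (permutation p = 0.249). For 25 restricted to thalamus-projecting cells it was 0.3132, above the 95th percentile of 0.2057 (permutation p = 0.00790). Some of these genes had reads in the other group, such as Atp2b4 at 31.4 CPM in medulla-projecting cells. Such reads give a shared order under 1 share too, so the value does not decide against 1 share. With the 2 gene sets apart, the test cannot tell a mixture from cells of an intermediate kind, and single-cell RNA-seq of neurons labelled from the pons and superior colliculus could.

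For the other comparisons, 10 splits of superior colliculus and pons libraries are too few to exclude chance (1 gene in the real split, 0 in the highest other). A chance division of the libraries is unlikely for superior colliculus against medulla (1 of 84 splits, 56 genes, highest other 17) and pons against thalamus (1 of 84, 54 genes, highest other 6). These real splits are also splits by run, so they do not show an effect of target. For superior colliculus against thalamus (3 genes) and pons against medulla (5 genes), 3 of 84 splits each called as many, the real one included, but the highest other called 7 and 16. These 2 real counts lie within the range of other splits, so chance is not taken as excluded for them. The run could account for part or all of each of these 4.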
